A study of Mus musculus with 2 samples.

How the data were processed

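DNase-seq had been run on frontal cortex of male B6CASTF1/J mice aged 36 days, with 2 biological replicates in 1 group, numbered as the labels number them. The replicates are separate tissue samples per the labels, which give both the same donor entry at the level of the strain. Which animals each sample came from is not given in the sources used here. Read alignment, peak calling and footprint calling were done before deposit. The aligner, the peak and footprint callers and their versions are not given in the sources used here.

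Peaks were deposited in narrowPeak format on assembly mm10, called from each replicate's own alignment and not on pooled replicates, per the deposited description that accompanies each sample. Each peak has a signal value set by the authors, and the deposited values lie, within a small tolerance, at whole multiples of a step that differs between the replicates. The scale is not stated, so values were used to rank and describe peaks, and ratios between replicates were centred on the median of all shared regions. The deposited FDR column (a q value for each interval of a few bases) lists intervals under 0.05 only, and the deposited footprints carry a constant value of 0.01, read as the FDR limit of the call by the authors.

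The authors deposited 2 peak lists per replicate. Every peak of the smaller list held a base with FDR under 0.001, and every peak of the larger list held a base under 0.05. The plan named the narrower list as main and the broader as alternative, but both are narrowPeak lists of similar width (median 200 bp in each smaller list, 201 and 209 bp in the larger). The smaller list was taken as main after the files were looked at, and the larger one, with 182994 and 162222 peaks, as the alternative. Intervals under an FDR of 0.001 covered 35.7 and 31.6 Mb, with a Jaccard index of 0.634 between replicates.

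Gene models came from GENCODE mouse release 21 (vM21) on the assembly of the files, with 21938 protein-coding genes on 21 chromosomes. Overlaps were computed with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15, in place of bedtools, which the plan had named. Figures were drawn with matplotlib 3.10.9. Peaks were shared when they overlapped by at least 1 bp. A shared region is the union of overlapping peaks of both replicates, with the highest value of each. The chance level came from 100 random circular shifts of at least 1 Mb. Peaks were assigned to promoters, exons, introns and intergenic sequence by their midpoint. A promoter was open when a peak overlapped the 500 bp on either side of any annotated start site of the gene, and distal peaks were those outside all such windows.

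The 23 gene lists, the tests, the motif consensus sequences, the rule for named genes and most alternative settings were fixed before the data were examined. Some genes belong to several lists, so calls of such lists are not separate results. Cux2 is in the excitatory neuron and upper layer lists, and Fezf2 and Tbr1 are in the excitatory neuron and deep layer lists. Hoxa2, Hoxb2 and Hoxb4 are in the hindbrain and Hox lists. Promoter lists were tested with a two-sided Fisher's exact test against all other protein-coding genes. Genes were not matched on the number of annotated start sites, and a gene with more of them has more windows in which a peak can lie. Distal lists were tested by permutation against 10000 random lists matched on decile of locus length. Benjamini-Hochberg adjustment ran over the lists within a replicate, and a list was called when the adjusted value was below 0.05 in the same direction in both replicates. The replicate ratio of a list is the median over its distinct shared regions, with its percentile among 10000 random lists matched on decile of the number of shared regions, a matching the plan left open. All random lists were drawn with replacement within deciles. A first version took the median of each gene before that of the list. It was replaced, after its values had been seen, by the form the plan states, and is kept as an alternative.

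Motif matches were counted on both strands in all footprints, including those outside peaks, and in peak bases outside footprints. A motif was called when the ratio exceeded 1.5 in both replicates. Intervals are exact 95% binomial (Clopper-Pearson) intervals, which cover counting error only. Up to 10 shuffles of each consensus were counted in the same way, an addition made after seeing the data. The promoters of a gene were taken as CpG-rich when the highest observed over expected ratio among its start sites was at least 0.6. This held for 52.5% of protein-coding genes, and all start sites of such a gene were included. Named genes are, for each list, the 4 with most shared regions and the first 3 in alphabetical order without a promoter peak in either replicate, plus Slc17a7, Gad1, Gfap, Mbp, Cx3cr1 and Cldn5. Genome-wide, the 10 genes with most shared regions and the 10 highest shared regions by mean rank were named. A few genes that this rule picks are left out of the text. Other named genes were chosen after their values were seen. Alternatives tried were promoter windows of 200 and 2000 bp, reciprocal overlap, other locus flanks, the mean in place of the median, the larger list, the higher-valued 50% of peaks, equal numbers of peaks, CpG-rich promoters, other footprint backgrounds and each replicate alone.

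Bmal1 was matched to Arntl. H19, Meg3, Kcnq1ot1 and Airn are not protein-coding in the annotation and were left out of the imprinted list. The steps were tested on simulated data. With 20 planted and 20 unchanged lists of 16 genes among 21938 genes, the promoter test recovered 20 lists made fully open and 19 made mostly closed. The distal test recovered 1 list with 2-fold and 11 lists with 3-fold more peaks. None of the unchanged lists was called in any of these runs. The simulated replicates were drawn independently of each other, whereas 59.9% of protein-coding genes were open in both real replicates. These runs therefore do not give the rate of false calls or the power for these data. A planted overlap of 75.1% was recovered in full, and a planted motif ratio of 80.2 came back as 79.4. A stricter set of footprints could not be formed, since the files give no value per footprint. Signal tracks and alignments were not used here.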

Results

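Accessible chromatin was mapped by DNase-seq, in which DNase I cuts exposed DNA in isolated nuclei and the cut ends are sequenced. The tissue was frontal cortex, the anterior part of the cerebral cortex, from male mice aged 36 days of the hybrid strain B6CASTF1/J. The labels give 1 group with 2 biological replicates, so no conditions were compared. The comparisons below set the replicates against each other, and set gene groups, regions and chromosomes against one another within each replicate. For each replicate the data are peaks of accessibility, footprints (short protected stretches inside accessible DNA) and a false discovery rate per small interval, all on mouse assembly mm10. The number of sequenced reads was not used here. Peak values lay at or close to whole multiples of a step, 0.00731 in replicate 1 and 0.00623 in replicate 2, and the median peak held 129 and 139 steps. If a step is 1 read, counting error alone is 8.80% and 8.48% of the median value.

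Among the 10 shared regions with the highest mean rank of the authors' peak value, the promoters of Hjurp (a chaperone of centromeric histone), Rab11b (recycling endosomes), Acin1 (RNA processing), Prmt5 (an arginine methyltransferase) and Hnrnpc (an RNA-binding protein, start site 253 bp away) each held 1. The Hjurp region, chromosome 1 from 88277521 to 88277760, had values of 29.6 in replicate 1 and 20.98 in replicate 2. The Rab11b region, chromosome 17 from 33760381 to 33760640, had 21.8 and 16.2. The highest values of all, 44.6 and 72.1, were at an annotated ribosomal RNA gene on chromosome 17 from 39846781 to 39846920. An exon of Lars2, the mitochondrial leucyl-tRNA synthetase, held 23.0 and 44.4 at chromosome 9 from 123461881 to 123462160. The other 3 regions lay in the pseudogene 2610005L07Rik and in intergenic sequence on chromosomes 3 and 6.

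Shared regions were also counted per gene locus (gene body plus 10 kb each side). The RNA splicing regulator Rbfox1 and the ion channel gene Asic2 had 58 each, the synaptic adhesion gene Nrxn3 had 56 and the postsynaptic scaffold gene Dlg2 had 54. Camta1 and Csmd1 had 53 each and Auts2 had 49. The gene models Gm20388 (303 regions), Fgfr2 (136) and Gm37240 (68) ranked above them, and their annotated spans run across neighbouring genes, which adds the neighbours' regions to their counts. Locus counts were not scaled by gene length.

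Peaks were largely shared between the replicates, and promoter peaks more so than others. Replicate 1 had 113082 peaks and replicate 2 had 96803. Of these, 71.8% of replicate 1 peaks and 83.9% of replicate 2 peaks overlapped a peak of the other by at least 1 bp, a mean of 77.9%. In 100 random shifts of the peaks along their chromosomes the mean overlap was 1.68% and the highest 1.80%. Peaks at promoters of protein-coding genes were shared in 86.5% and 87.4% of cases, and the remaining peaks in 68.3% and 82.9%. Shared peaks had median values of 1.22 and 0.991, against 0.555 and 0.499 for unshared peaks. Across the 79118 shared regions, Spearman's rho of the values was 0.908, a description across regions, which are not independent replicates. The median log2 ratio of replicate 2 over replicate 1 was −0.31, with an SD across regions of 0.42. When both peaks had to overlap by 50% of their length, the mean share was 64.9%.

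Accessible sites were concentrated at gene starts. Promoters, taken as 500 bp each side of a start site of a protein-coding gene, held 19.2% ± 1.99 of peaks (SD, n = 2) and make up 2.02% of the genome, a 9.52-fold ± 0.983 excess. Exons held 6.16% ± 0.309 of peaks against 4.10% of the genome, introns 39.4% ± 1.51 against 40.2%, and intergenic sequence 35.2% ± 0.786 against 53.6%. Promoter peaks also had higher values, with a median of 1.94 against 0.848 elsewhere in replicate 1 and 1.57 against 0.779 in replicate 2. Of 21938 protein-coding genes, 62.0% had a promoter peak in replicate 1, 61.2% in replicate 2 and 59.9% in both. The promoter share depended on the list of peaks used and was 14.1% in the authors' larger list and 28.6% in the higher-valued 50% of peaks.

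Promoters of activity-regulated, circadian clock and housekeeping genes were open without exception in both replicates, while promoters of genes specific to other organs were mostly closed. All 19 activity-regulated genes, which neurons switch on when stimulated, carried a promoter peak, with values at Egr4 of 6.50 and 3.49 and at Junb of 7.13 and 4.69. All 16 clock genes did too, among them Per1 (18.0 and 12.1), Per2 (11.9 and 9.34) and Arntl (10.5 and 6.64), as did all 18 housekeeping genes, including Actb (13.2 and 7.15) and Rplp0 (16.1 and 12.4). Synapse genes followed with 22 and 21 of 22, including Nrxn3, Nlgn1 and the scaffold gene Shank2, and upper cortical layer genes with 13 of 14 in each replicate. The upper layer transcription factor gene Cux1 had promoter values of 2.35 and 1.81, Lmo4 had 6.23 and 4.15, and Rspo1 was the layer gene without a peak. Each of these 5 lists passed a two-sided Fisher's exact test against all other protein-coding genes in both replicates, and the upper layer list lost its call with a 200 bp window and in the larger list of peaks. Adjusted exact p values (Benjamini-Hochberg over 23 lists) were 0.000618 and 0.000707 for activity-regulated, 0.00230 and 0.00121 for clock, and 0.000888 and 0.00110 for housekeeping genes. They were 0.000238 and 0.00133 for synapse and 0.0387 and 0.0233 for upper layer genes, again by the exact test.

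At the other end, 6 lists had fewer open promoters than other genes in both replicates. A promoter peak was found at 1 of 39 Hox genes, the body-axis transcription factors, and at 36 and 29 of 1464 olfactory and vomeronasal receptor genes. Liver genes had 2 of 16 in each replicate, with Alb (albumin), Apoa1 and Ahsg closed and Apoh open with values of 6.42 and 4.26. Muscle and heart genes had 2 of 14 in each, with Actc1, Acta1 and Ckm closed and Tnni3 open at 0.818 and 0.723. Blood genes had 4 and 2 of 16, with Cd3e and Cd79a closed and Pax5 and Epor open in both. Germline genes had 2 of 14, with Ddx4, Acrv1 and Mael closed and Dazl and Gdf9 open. The adjusted exact p was 2.91e-14 and 6.01e-14 for Hox, 0.000375 and 0.000482 for liver, and 0.000888 and 0.00121 for both muscle and germline lists. It was 0.00658 and 0.000482 for blood in the exact test, and too small to be represented for the receptor genes.

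Markers of single brain cell classes were less uniform, and 12 lists were not called. In the larger list of peaks the excitatory neuron and astrocyte lists were called higher. Excitatory neuron genes were open in 14 and 12 of 14 and deep layer genes in 14 and 12 of 15. The vesicular glutamate transporter gene Slc17a7 was open in both replicates, at the first start site in replicate 1 (1.88) and at a downstream start site in both (1.53 and 1.84), as were Camk2a (5.11 and 3.68) and the deep layer regulators Sox5, Bcl11b, Foxp2 and Ldb2. Inhibitory neuron genes were open in 16 and 11 of 20. Gad1, the GABA-synthesising enzyme gene, had no peak within 500 bp of a start site in either replicate, its nearest peaks lying 762 and 785 bp away. Lhx6 and Sst were also closed, while Sox6, Adarb2 and Reln were open in both. Astrocyte genes were open in 13 and 12 of 15, with Gfap at 1.66 and 2.14 and Aqp4 and Fgfr3 closed. Oligodendrocyte genes were open in 12 and 7 of 16, with Mbp (myelin basic protein) open in replicate 1 alone, Olig1 and Mog open in both, and Aspa and Opalin closed. Precursor genes were open in 10 and 9 of 11, with Pcdh15, Lhfpl3 and Vcan open and Cspg4 closed. Microglia genes were open in 7 and 4 of 16. Cx3cr1, the fractalkine receptor gene, was open in replicate 1 alone, Aif1 in both, and C1qa, C1qb, Csf1r and P2ry12 in neither. Endothelium and pericyte genes were open in 6 of 16 in each, with the glucose transporter gene Slc2a1 open and Cldn5, Cdh5, Flt1 and Pecam1 closed.

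Striatum genes were open in 11 and 9 of 12, including Pde10a, Ppp1r1b, Rgs9 and Foxp1, the last of which cortical neurons also express. Choroid plexus and ependyma genes were open in 4 and 2 of 11, with Prlr open and Clic6, Kcnj13 and Ccdc153 closed. Hindbrain and cerebellum genes were open in 2 and 5 of 15, with Egr2, also in the activity-regulated list, open in both and En1, Gabra6 and Barhl1 closed. Imprinted genes were open in 13 of 16 in each, with Igf2r, Snrpn, Peg10 and Peg3 open and Dlk1, Igf2 and Ndn closed. The exact test passed in replicate 1 alone for the excitatory neuron list (adjusted exact p 0.00331 against 0.138), the deep layer list (0.0243 against 0.225) and the hindbrain list (0.000618 against 0.0550). It passed in replicate 2 alone for the microglia list (adjusted exact p 0.204 against 0.00831) and the choroid plexus list (0.135 against 0.00882). Genes are not independent replicates, so these p values describe lists within these libraries. Among genes with CpG-rich promoters alone, of which 92.6% of other genes were open in replicate 1, none of the 5 lists kept its higher call, and 3 lists (Hox, germline, and hindbrain and cerebellum) were called lower.

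**Figure D1:**
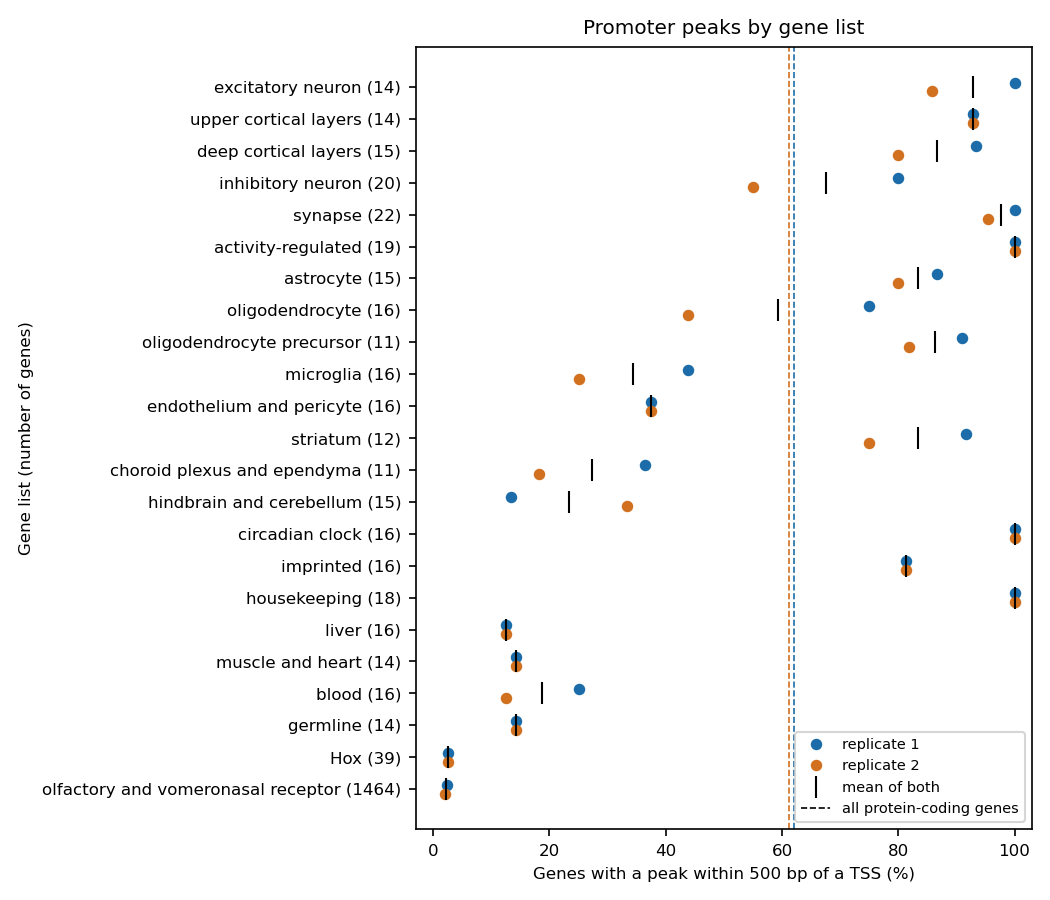
Share of genes in each of the 23 lists with a peak within 500 bp of a start site, for replicate 1 and replicate 2 (points) and their mean (vertical marks), with the share of all protein-coding genes as dashed lines at 62.0% and 61.2%. Activity-regulated, clock and housekeeping lists sit at 100% in both replicates, and Hox and receptor lists under 3%.

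Away from promoters, loci of upper cortical layer, excitatory neuron, activity-regulated and clock genes held more accessible sites than loci of similar length. Upper cortical layer genes had a median of 7 and 8 distal peaks per locus, against medians of 2.5 and 2 for random lists matched on locus length. Activity-regulated genes had 4 and 5 against 1, with 11 distal peaks at Egr4 in each replicate and 5 at Junb. Clock genes had 5 and 4.5 against 2 and 1.5, with 11 and 14 at Per1 and 12 and 11 at Arntl. Excitatory neuron genes had 5 in each replicate against 2, with 11 and 15 at Cux2, also in the upper layer list, and 15 and 8 at Camk2a. These 4 lists were called higher, with adjusted permutation p values of 0.00552 and 0.00230 for upper layer, 0.00230 in both replicates for activity-regulated, 0.00230 and 0.00460 for clock, and 0.0276 and 0.00920 for excitatory neuron genes. The smallest unadjusted p that 10000 random lists can give is 0.0002 in this two-sided permutation test.

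Synapse genes had 12 and 7.5 distal peaks per locus against 5.5 and 4.5, and passed in replicate 1 alone (adjusted permutation p 0.00230 against 0.0800). Nrxn3 had 75 and 58 distal peaks and Shank2 had 45 and 41. Medians of the glial lists were 2 in each replicate for astrocyte and microglia genes, 2.5 in each for oligodendrocyte genes and 7 and 5 for precursor genes, none of them called. Inhibitory neuron genes had 3 and 1.5, deep layer genes 3 in each, endothelium and pericyte genes 2.5 and 2, striatum genes 2.5 and 2, and choroid plexus and ependyma genes 2 and 0. Imprinted genes had 2.5 in each, muscle and heart genes 1.5 and 2, housekeeping genes 1 and 2, and liver, blood, germline, and hindbrain and cerebellum genes 1 in each, with no call. Hox genes had 0 and 1 and receptor genes 0 in each, and receptor genes passed as lower in replicate 1 alone (adjusted permutation p 0.00230 against 0.399). Excitatory neuron and upper layer lists lost their call with 50 kb flanks and in the higher-valued 50% of peaks, where the synapse list was called higher, and the excitatory neuron list also with equal numbers of peaks. Counted in the gene body alone, no list was called in either direction, and with the mean in place of the median the activity-regulated list alone was called higher and the receptor list lower. In simulations with independently drawn replicates, the test recovered 11 of 20 lists with 3-fold more peaks and 1 of 20 with 2-fold more. The power in these data was not measured, and lists without a call can still differ.

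**Figure D2:**
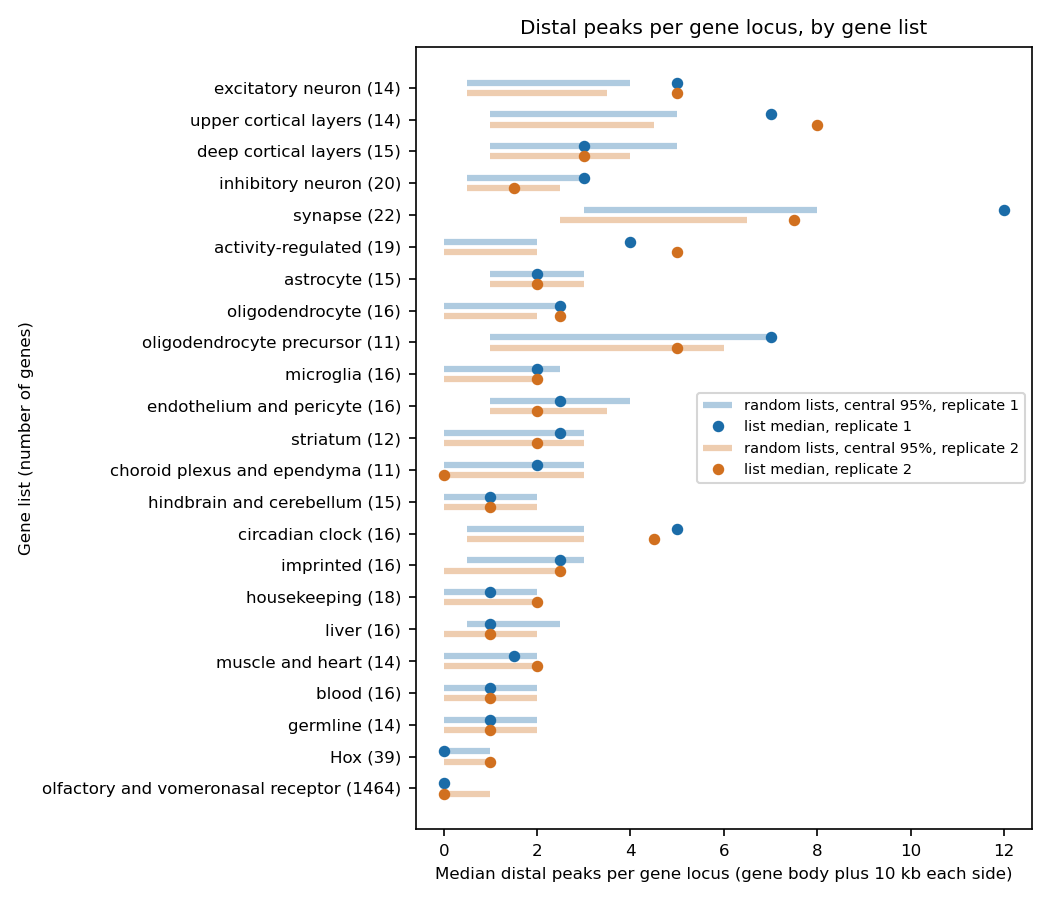
Median number of distal peaks per gene locus in each list (points) beside the central 95% of 10000 random lists matched on locus length (pale bars), for replicate 1 and replicate 2. Upper layer, activity-regulated, clock and excitatory neuron genes lie to the right of the bars in both replicates, as do synapse genes, which were not called.

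**Figure D3:**
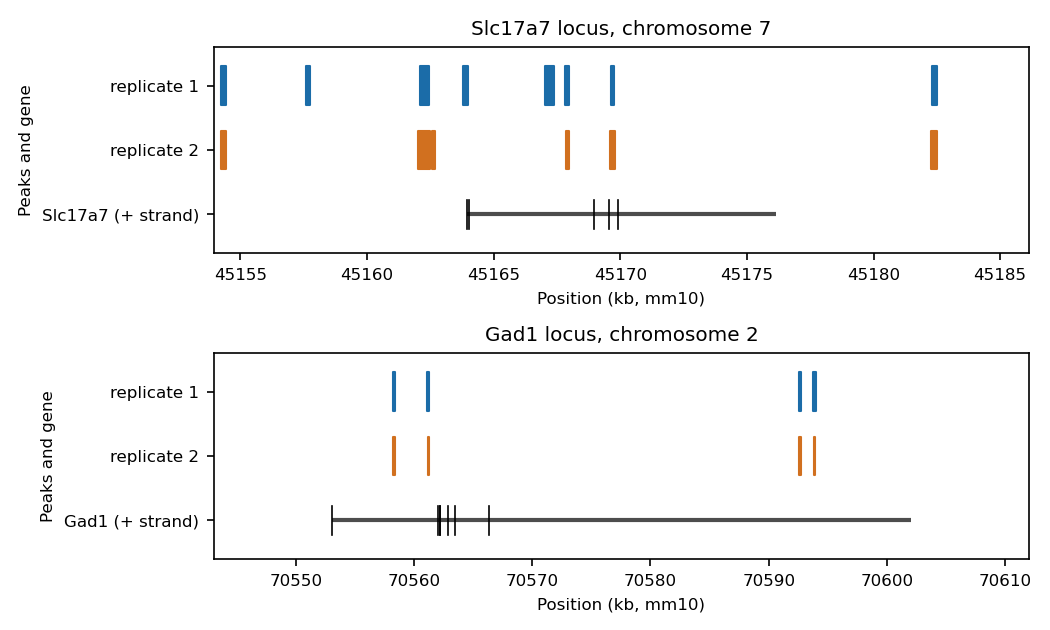
Peaks of replicate 1 and replicate 2 at Slc17a7 (chromosome 7, 45163949 to 45176142) and Gad1 (chromosome 2, 70553072 to 70602014), with the gene as a line, its annotated start sites as ticks and 10 kb on each side. At Slc17a7 a peak covers the first start site in replicate 1 alone, and a peak near a downstream start site is present in both, while the 4 Gad1 peaks of each replicate lie between start sites or downstream of them.

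Loci of Hox, muscle and heart, and receptor genes had a higher relative signal in replicate 2, and the other 20 lists lay inside the range of random lists. Of the 3 named lists, Hox loci alone stayed outside the range with promoter regions left out. After the median over all shared regions was subtracted, the log2 ratio of replicate 2 over replicate 1 was 0.06 for excitatory neuron, 0.06 for upper layer, −0.01 for deep layer, 0.10 for inhibitory neuron and −0.07 for synapse loci. It was 0.02 for astrocyte, −0.06 for oligodendrocyte, 0.03 for precursor, −0.06 for microglia and −0.05 for endothelium and pericyte loci. Each of these lay inside the central 95% of matched random lists, as did striatum (0.05), choroid plexus (0.12), hindbrain (0.16), activity-regulated (−0.01), clock (−0.09), imprinted (0.11), housekeeping (−0.06), liver (0.16), blood (−0.01) and germline (0.14). Hox loci stood at 0.61, above all 10000 random lists (percentile 100, central 95% from −0.15 to 0.21), with 9 of their 10 shared regions above 0. The 19 Hox genes share these regions, so random lists of as many genes hold more distinct regions, which narrows that range. Muscle and heart loci stood at 0.25 (percentile 99.3) and receptor loci at 0.10 (percentile 99.9), and with promoter regions left out both fell inside the range of the random lists (percentiles 86.1 and 46.8) at similar values of 0.23 and 0.12. In the larger list of peaks, muscle and heart loci (percentile 91.2) and receptor loci (96.0) lay inside the range, and upper layer (0.11, percentile 99.2), hindbrain (0.25, percentile 99.2), germline (0.20, percentile 98.4) and clock loci (−0.10, percentile 1.68) lay outside it with Hox. These are descriptions of 2 libraries without a test, in the authors' units, whose scale is not given in the sources used here.

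The X chromosome, present in a single copy in these males, carried fewer and lower peaks than the autosomes. There were 16.9 and 15.2 peaks per Mb on X against 44.7 and 38.2 over the autosomes, whose lowest single values were 38.0 and 31.8. Of 948 X-linked protein-coding genes, 47.6% and 46.9% had a promoter peak, against 63.2% and 62.4% of 20807 autosomal genes. The odds ratio was 0.529 and 0.533, with two-sided Fisher's exact p of 1.48e-21 and 4.05e-21, and genes are not independent replicates. Median values of promoter peaks on X were 0.610 and 0.560 of those on autosomes, and 0.585 and 0.594 away from promoters. Among genes with CpG-rich promoters, a setting chosen after seeing the data, the share open was 88.1% and 89.1% on X against 92.7% and 92.5% on autosomes, a mean difference of −4.04 points in place of −15.5.

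**Figure D4:**
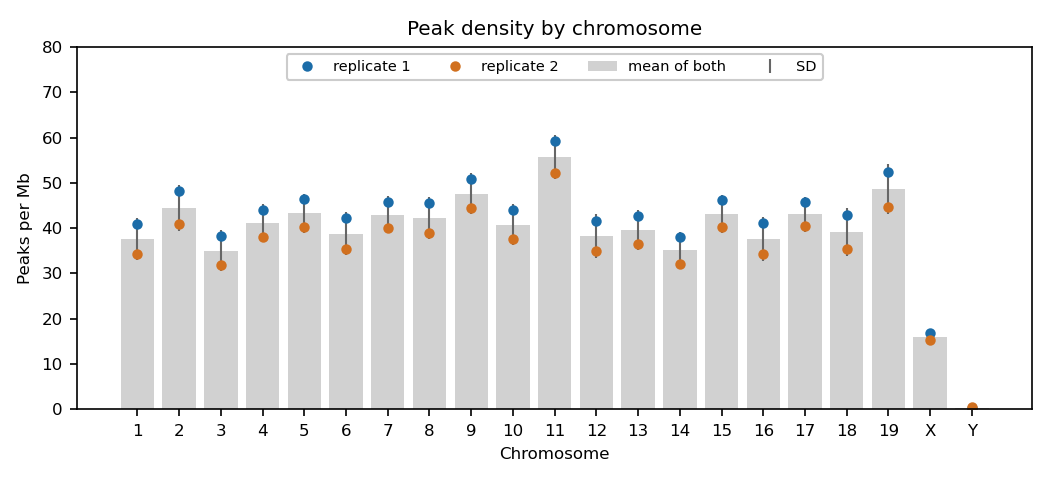
Peaks per Mb on each chromosome for replicate 1 and replicate 2 (points), with the mean of both as bars and the SD as error bars (n = 2). Chromosome X, at 16.9 and 15.2, lies below every autosome, and chromosome Y holds 22 and 36 peaks in all.

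Footprints marked protected sites about the width of a transcription factor contact inside accessible DNA. There were 396696 in replicate 1 and 409186 in replicate 2, with a median length of 9 bp in each. Of these, 73.0% and 67.1% lay inside peaks (mean 70.1% ± 4.17 SD, n = 2), and 24.5% and 26.1% lay in promoters of protein-coding genes. Footprints overlapped a footprint of the other replicate in 47.3% and 44.8% of cases, against 0.349% when shifted along chromosomes. Within peak sequence common to both replicates, the mean was 61.3% against 34.0% by random shifts. These shifts moved footprints into other peaks. They make no allowance for which peaks, or which parts of a peak, footprints tend to lie in. The overlap was 32.9% when both footprints had to share 50% of their length. Footprints held 59.9% and 60.4% G and C bases, and peaks 52.5% and 53.4%.

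Binding motifs of CTCF, NRF1, RFX, NFI and CRE were the most concentrated inside footprints. The consensus of CTCF, the insulator protein, was found 39.0 and 54.2 times as often per kb in footprints as in peak bases outside footprints. That of NRF1, a regulator of mitochondrial genes, was found 109 and 53.4 times as often. Footprints outside peaks were counted too. RFX (ratios of 32.0 and 45.6), NFI (14.2 and 20.02) and CRE, the site of CREB factors (14.3 and 19.2), followed. YY1, at 6.69 and 4.41, stood below EGR and SP/KLF. EGR, the site of activity-induced zinc finger factors, had ratios of 10.3 and 10.2, with shuffled versions of its consensus reaching 7.71, and the neuronal bHLH site of NEUROD-type factors 3.37 and 3.50, with 6384 and 6588 matches in footprints. The shorter E-box CATCTG had ratios of 2.00 and 2.09, and lost its call when footprints were widened by 10 bp. On the other strand this E-box lies within the neuronal bHLH consensus CAGATGG, so every match of the longer site counts for both. The E-box was not counted without those matches, so its ratio is not a separate result. Widening also lowered most of the other called motifs, among them EGR to 5.28 and 4.80, CRE to 9.32 and 10.1 and NFI to 7.76 and 7.91. RFX fell to 17.0 and 27.9, NRF1 to 69.8 and 40.3 and CTCF to 26.9 and 34.5. SP/KLF had 9.64 and 9.61 and ETS 2.84 and 2.54, but a shuffled consensus of the same bases reached 10.3 and 5.21, so neither exceeded its highest shuffle. REST, the repressor of neuronal genes in other tissues, had 2.53 and 4.55 from 9 and 15 matches, and the exact 95% binomial interval in replicate 1 ran from 0.976 to 6.17.

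The GATA, HNF4 and PU.1 motifs, of factors that act mainly in blood or liver, did not exceed the limit of 1.5. GATA had ratios of 0.413 and 0.374, HNF4 0.732 and 1.12 and PU.1, a macrophage and microglia factor, 1.22 and 1.16. HNF1 and OCT4-SOX2 had 0 matches in footprints, with 2 and 1 OCT4-SOX2 matches elsewhere in peaks, so no ratio was formed and enrichment cannot be judged for them. AP-1 stood at 1.23 and 1.04, MEF2 at 1.43 and 0.995, TBR1 at 1.47 and 1.39, SOX at 0.781 and 0.745, TEAD at 0.928 and 0.746 and LIM homeobox at 0.531 and 0.406, all under the limit of 1.5 in both replicates. Of the motifs under the limit, TBR1 and MEF2 exceeded all their shuffles in both replicates (highest 1.05 and 0.934), and TBR1 passed the limit in footprints outside promoters (1.72 and 1.59). Footprints are richer in G and C bases than peaks, and the limit of 1.5 makes no allowance for this. For the called motifs RFX, YY1 and REST no shuffled ratio could be formed, so base composition was not checked for them. Shuffles of GATA had median ratios of 0.471 and 0.444, and GATA and LIM homeobox stood below the medians of their shuffles. AP-1 (shuffle medians 0.595 and 0.573), PU.1 (0.654 and 0.558), SOX, HNF4 and TEAD stood above theirs. The highest shuffles of AP-1 and PU.1 reached 1.67 and 1.42, so some concentration in footprints is neither shown nor excluded for them. In all, 12 of the 23 consensus sequences exceeded 1.5 in both replicates, with the neuronal bHLH site and the E-box nested in it both among the 12. A consensus match does not show which protein was bound, and intervals cover counting error only.

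**Figure D5:**
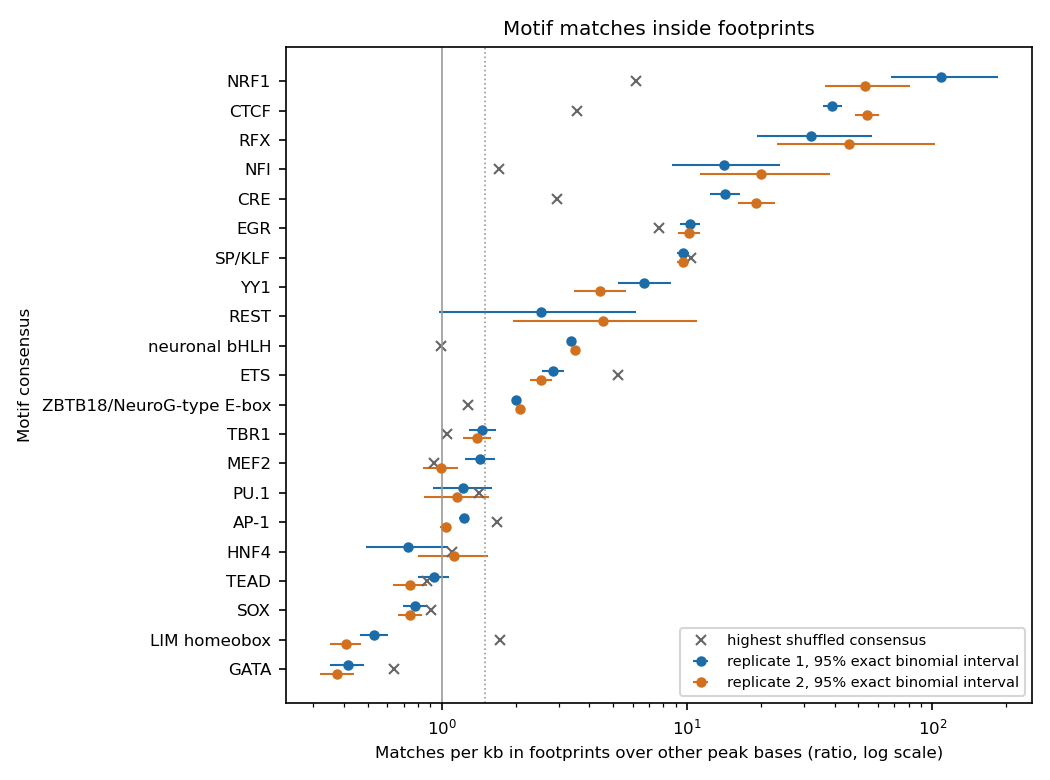
Ratio of motif matches per kb in footprints to peak bases outside footprints, on a log axis, for replicate 1 and replicate 2 (points with exact 95% binomial intervals), beside the highest ratio of shuffled consensus sequences where one could be formed (crosses). NRF1 at 109 and 53.4 and CTCF at 39.0 and 54.2 lie far above their crosses, and SP/KLF and ETS lie at or under theirs.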

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

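The tests of a single X copy and of peak value at muscle and heart and receptor loci were chosen after the result was seen, as were the settings with lists matched on value or GC content and with CpG-rich promoters on X, and every pattern weighed here was noticed in the same data.

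The Y chromosome, which is left out of the comparison of X with autosomes and has none of its own, held 22 peaks in replicate 1 and 36 in replicate 2. No background count was formed to set these numbers against. These peaks and the Y genes are part of the totals used elsewhere. Of 183 protein-coding genes on Y, 4 had a promoter peak, the same 4 in both replicates: Kdm5d, Eif2s3y, Uty and Ddx3y, genes with X-linked partners that are expressed in many tissues. Most of the Y-linked genes belong to repeated families, to which short reads are hard to assign.

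Across all shared regions 23.5% had a higher value in replicate 2. Among the 10 highest 4 did, a small count that was not tested against that share. These 4 lay at the ribosomal RNA gene on chromosome 17, at Lars2 and in intergenic sequence on chromosomes 3 and 6. If reads from repeated copies pile up there, the sequence should recur elsewhere in the genome, and a median of 76.4% of the 31-base words in these 4 regions did so, against medians of 0% in the other 6 and 0% in 200 random shared regions. Reads shared between copies in the reference are a candidate explanation for the height of these sites, and copies missing from the reference were not tested. Repetition alone does not separate the replicates, since the pseudogene 2610005L07Rik on chromosome 8, at 80.5%, was slightly higher in replicate 1. How reads with several matches were treated is not given in the sources used here, and no biological explanation was tested.

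Hox loci had a higher relative value in replicate 2, by 0.61 on the log2 scale, in 9 of 10 regions spread over 4 clusters. The list stayed high among lists matched on peak value (percentile 100) or on GC content (percentile 100). Among 10000 draws of blocks of neighbouring regions it stood at percentile 99.97. The 19 Hox genes share 10 regions, and the value-matched and GC-matched lists were not matched on number of regions. Their central 95% (−0.10 to 0.12 and −0.10 to 0.13) is thus too narrow, against −0.30 to 0.33 for the blocks. In 5 groups of all shared regions ranked by value, the median ratio ran from 0.07 in the lowest to −0.10 in the highest. By GC content it ran from 0.06 to −0.08. The value of 0.61 lies beyond the medians of these groups and the central 95% of the blocks, although the highest block draw reached 0.68. The blocks argue against clustering as the sole cause. They were not matched on value or GC content, and the lists that were matched held more regions. A part for value or GC content together with clustering was therefore not tested. Muscle and heart and receptor loci also stayed high against value-matched lists, at percentiles 99.67 and 99.84. With promoter regions left out they fell inside the range at similar medians (0.23 and 0.12), at percentiles 86.1 and 46.8. Outside promoters, then, neither list stood apart from matched loci. In the larger list of peaks muscle and heart loci stood at 0.12 (percentile 91.2) and receptor loci at 0.07 (percentile 96.0). Of 23 lists, about 1 would lie outside the central 95% by chance. A difference between the animals, the dissections or the digestion of the nuclei may underlie the Hox values, and the design, with 1 library each, leaves these open.

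Peak values on X were lower than on autosomes. A split by promoter CpG content did not remove this. Among peaks at start sites of genes with a CpG-rich promoter the ratio was 0.661 in replicate 1 and 0.592 in replicate 2. Single autosomes ranged from 0.781 to 1.20 and from 0.863 to 1.25. The split is coarse, since it includes CpG-poor start sites of these genes, and CpG content was not matched between X and autosomes within it. A part for CpG content therefore stays open. The X ratios of 0.661 and 0.592 lie within the range set for a single copy of X, so copy number may account for the lower values. The range allowed for that test was set after the overall X ratios were known. Strain names give the mother first by convention, which would make X the B6 copy, but the labels do not state the cross and mapping was not tested, so lower mapping of a CAST copy stays open. Differences in the kinds of genes on X stay open too.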

How the results depend on the processing

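The settings with CpG-rich promoters for X, with lists matched on value or GC content, and with the median of each gene first were chosen after the data were seen; the others were planned. Over these settings, 50 values that answer a comparison stayed and 22 moved. Staying meant within their spread, on their side of the test or, for counts of lists or motifs called, within 1.5-fold of the main count. Such a count can stay while the lists behind it change, as the higher distal calls did with 50 kb flanks. Where a value moved, the cause was not tested unless it is named here. The X difference stayed negative and past the exact test in every setting run, from −21.1 to −14.8 points and at −4.04 among CpG-rich promoters, and 11 to 13 motifs were called (E-box CATCTG lost in widened footprints, TBR1 gained outside promoters). With 2 replicates, leaving out either moves a mean by a fixed part of its SD, so for values with an SD this shows nothing about stability. Such values are nevertheless counted among the 50. Stricter footprints were not run, for sharing or for motifs, because all footprints carry the same value, and sharing has no value with a replicate left out. No paired analysis was possible because there is 1 group.

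Sharing of peaks was 64.9% with reciprocal overlap of 50%, and that of footprints 32.9%, rising to 49.3% inside peaks only. Spearman's rho was 0.910 with reciprocal overlap, 0.912 in the larger list, 0.845 in the higher-valued 50% of peaks and 0.894 with the same number of top peaks. Promoters held 14.3% of peaks with a window of 200 bp, 28.7% with 2000 bp, 14.1% in the larger list and 28.6% in the higher-valued 50%.

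The upper layer list lost its promoter call with a 200 bp window and in the larger list. In the larger list the excitatory neuron and astrocyte lists gained a higher promoter call, and with the 200 bp window the hindbrain list gained a lower one. Among CpG-rich promoters, 0 promoter lists were called higher and 3 lower; nearly all such promoters are open, so a higher call has little room. In the higher-valued 50% of peaks 10 lists were called lower. For distal peaks, gene bodies alone gave 0 higher calls, 50 kb flanks gave 1 lower, the mean gave 1 higher and 1 lower, and the larger list gave 1 lower, the receptor genes each time for the lower call. Leaving out each replicate gave 0 to 1 lower distal calls. With 50 kb flanks and in the higher-valued 50% of peaks the excitatory neuron and upper layer lists lost their distal call and the synapse list gained one, as it did in the larger list and without replicate 2. Lists outside the central 95% of the replicate ratio numbered 1 with promoter regions left out and 5 in the larger list, upper layer, hindbrain, clock, germline and Hox. They numbered 4 in the higher-valued 50% of peaks, with imprinted loci gained (percentile 99.6 in place of 94.9), and 4 among value-matched lists, with germline loci gained (98.0 in place of 89.3). With the median of each gene first, striatum (percentile 98.7 in place of 78.2) and clock loci (2.25 in place of 5.38) lay outside and muscle and receptor loci inside.

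Some lists changed sign. Differences in open promoters from other genes, in percentage points, became −0.826 for excitatory neuron, −0.826 for upper layer, −3.61 for deep layer, −23.3 for inhibitory neuron, −9.16 for astrocyte, −17.5 for striatum and −9.17 for imprinted genes among CpG-rich promoters. There, microglia (3 genes), liver (2) and blood (1) stood at 7.51. Of these the upper layer, liver and blood lists had been called. Inhibitory neuron genes were at −1.94 with a 200 bp window and −12.9 in the higher-valued 50%, where astrocyte genes were at −5.43. Oligodendrocyte genes were at 2.46 with 2000 bp and 9.01 in the larger list. Leaving out each replicate, inhibitory neuron genes ranged from −6.26 to 18.0 and oligodendrocyte genes from −17.5 to 13.0.

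None of the distal lists that changed sign had been called. Their percentiles minus 50 were, for gene bodies alone, −10.1 for microglia, 8.29 for choroid plexus, −1.07 for hindbrain, −1.67 for housekeeping, −0.955 for blood and −3.73 for germline genes. With 50 kb flanks they were −25.9 for striatum, −32.5 for hindbrain and 27.2 for liver genes. With the mean they were −27.1 for endothelium, −38.2 for hindbrain and −2.02 for germline genes. In the larger list choroid plexus genes were at 34.1 and blood genes at −23.1. In the higher-valued 50% endothelium genes were at −35.9, hindbrain at −11.0 and blood at −13.9, and with the same number of top peaks endothelium genes were at −20.8. Leaving out each replicate, endothelium genes ranged from −0.995 to 5.17, Hox from −34.0 to 21.9 and choroid plexus genes from −44.9 to 25.4.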

Other observations

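The genes named in this part were chosen after the files were seen, and no explanation is offered for the values.

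Promoters of genes that do not code for protein were counted without a test. A peak lay within 500 bp of a start site at 19.2% ± 0.713 of 5854 lincRNA genes (SD, n = 2) and at 32.4% ± 0.191 of 2959 antisense genes. Micro RNA genes, 2202 in number, stood at 11.5% ± 0.835 and 9940 processed pseudogenes at 2.35% ± 0.270. Protein-coding genes stood at 61.6% ± 0.525. Meg3, Kcnq1ot1 and Airn, imprinted RNAs, were open in both replicates, as were Miat, Rmst, Malat1 and Neat1. H19, an imprinted RNA of fetal tissue, and Xist, the RNA of the inactive X, had no promoter peak in either replicate.

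Several marker genes changed with the list of peaks. In the larger list, Mbp and Cx3cr1 had a promoter peak in both replicates, Gad1 in replicate 1 alone and Cldn5 in replicate 2 alone. The nearest peak of the smaller list to a Cldn5 start site lay 18782 and 18734 bp away, and that of Mbp in replicate 2 lay 2776 bp away.

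The striatum list lay inside the range of random lists, at percentile 78.2. At 10 of its 12 genes shared regions were present, and 6 of these genes had a higher centred ratio in replicate 2. Penk stood at 0.59, Drd1 at 0.38 and Gpr6 at 0.34, while Foxp1 stood at −0.10, Drd2 and Pde10a at −0.02 and Ppp1r1b at 0.00.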
